A study of Homo sapiens with 8 samples.

How the data were processed

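RNA sequencing was carried out on primary human granulosa-lutein cells, the steroid-producing cells recovered with oocytes from ovarian follicles during fertility treatment. Per the labels' protocols, the cells were purified on a density gradient, cultured for 6 days in medium with 10% serum, then kept without serum and given hCG with or without T-5224 for 12 hours. The dose of T-5224 was not given in the sources used here. Per the labels, strand-specific libraries were made with a TruSeq kit and sequenced for 101 cycles, and the libraries stand for 4 independent experiments in each of 2 conditions. Whether the kit selected poly(A) RNA or removed ribosomal RNA was not given in the sources used here.

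The deposited values are whole-number counts of reads per gene, not normalized, which the authors made with featureCounts 1.5.0, per the file headers. Per the file headers, exons were counted by gene in the reverse-stranded setting (2) on the RefSeq annotation of the human build GRCh38.p6. The options listed there do not turn on the counting of reads with several alignments, so genes with near-identical copies can be undercounted. The submitters' processing notes name FastQC 0.11.4, Trimmomatic 0.33, STAR 2.5.0a, R 3.3.1 and edgeR 3.15.0, without their roles. The labels name 3 sequencing lanes, whereas each file header names input reads from 1 lane, and whether the deposited counts hold all lanes was not settled from the files.

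Each file held 44087 genes. Symbols were taken by gene identifier from a RefSeq gene table of GRCh38.p14, used for names only, and 39071 genes (88.6%) matched. The 5016 unmatched genes held 0.0814% of the counts and stayed in the tests under their identifiers. Coordinates are those of the deposited exon records on GRCh38.p6. The total count per library lay between 12425285 and 20772691. Intervals from read counts cover counting error only.

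The main test compared 4 hCG+T-5224 with 4 hCG libraries with edgeR 4.0.16 (R 4.3.3). Low genes were removed with filterByExpr, library sizes were scaled by TMM, and a robust quasi-likelihood F test was run with Benjamini-Hochberg adjustment at 0.05. The 14225 genes tested held 99.9% of the counts. Log2 fold changes are hCG+T-5224 minus hCG, and their standard errors were derived from the F statistics. CPM values were computed with the cpm function of edgeR after TMM scaling and are given as mean ± SD over the 4 libraries of a group. For genes with 1 to 3 reads over a group, the ratio of pooled reads is given with its exact 95% counting interval. Both are scaled by the summed TMM-scaled library sizes of the groups.

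The groups, the test, 27 gene lists, the rule for named genes and the main set of alternatives were fixed before the data were examined. Lists with at least 5 tested members (25 of 27) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Haemoglobin genes and mitochondrially encoded protein genes had 0 tested members, the latter because the counted features on the mitochondrial chromosome were ribosomal and transfer RNA genes. The named genes were the 12 largest rises and 12 largest falls among genes past the threshold with a symbol and an average log2 CPM of at least 1. To these were added up to 4 members of each list with the smallest p, the FOS and JUN genes, and a set of ovulation, steroid and cholesterol genes fixed by name. A few genes that this rule names are not reported here, though they stayed in the tests and lists. Mitochondrial RNA genes, the added lists and their members were chosen after their values or those of related genes were seen.

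On simulated counts with 200 changed genes, 3 runs of 13965 tested genes recovered 83.7% of 4-fold changes and 9.67% of 2-fold changes, with a mean of 5 false calls per run. Smaller changes could therefore pass unseen with 4 libraries per group. No pair of libraries agreed within sampling noise, so none was a repeat run of another and all 8 were kept. Alternatives were other normalizations, DESeq2 1.42.0, limma voom, other filters and thresholds, a block on the replicate number, and leaving out each library or numbered pair. Sample quality weights and removal of each library's trend on gene length were added after seeing the data. Outlying values were sought in each group of 4 by Dixon's gap ratio (above 0.829) on 4 library measures and on the CPM of each named gene. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Genes of the Y chromosome and XIST are not reported here.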

Results

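Gene expression was measured in cultured human granulosa-lutein cells given hCG or hCG together with T-5224, with 4 libraries in each group. hCG acts on the LH receptor and stands in for the surge that triggers ovulation. T-5224 is a small molecule described as an inhibitor of DNA binding by AP-1, a family of transcription factors built from FOS and JUN proteins. The comparison asks which genes of the hCG-treated cell respond to T-5224. It holds no group without hCG, no group with T-5224 alone and no measure of AP-1 binding. Dependence on FOS/AP-1 is therefore not separated from other actions of T-5224. Total counts per library were 16650732 to 20772691 with hCG and 12425285 to 16646153 with T-5224. T-5224 replicate 2 had the smallest total and listed 17006 genes with a read, against 20223 to 21362 in the other T-5224 libraries.

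**Figure D1:**
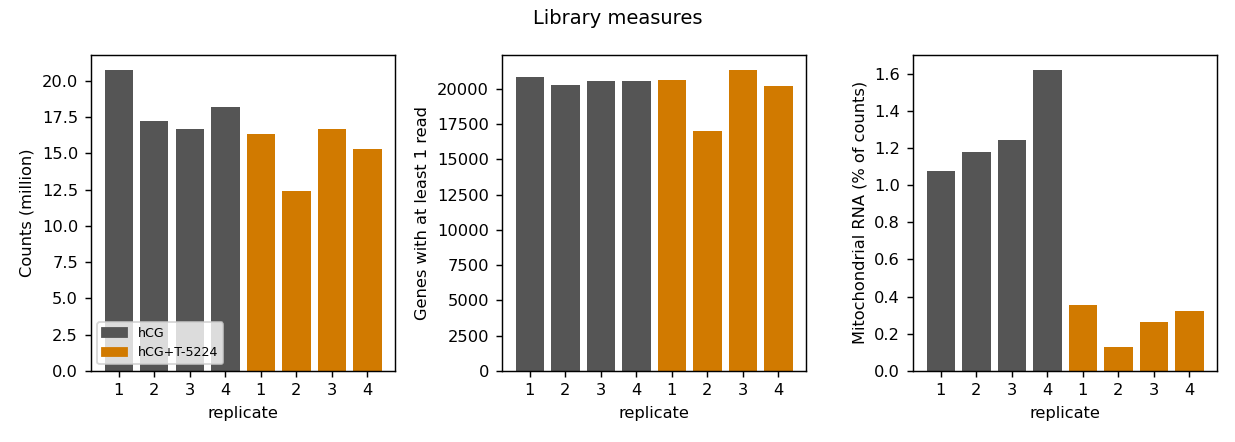
Total counts, genes with at least 1 read, and the percent of counts on mitochondrial RNA genes for each of the 8 libraries; each bar is 1 library. Mitochondrial ribosomal and transfer RNA genes, the only mitochondrial genes counted, took 1.08 to 1.62% of counts in the hCG libraries and 0.126 to 0.356% in the T-5224 libraries.

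CREB5, a bZIP transcription factor, rose 43.2-fold with T-5224, from 2.07 ± 0.725 to 89.7 ± 32.2 CPM (SD, n = 4 per group). GEM, a small GTPase, rose 42.2-fold and INHBA, the activin and inhibin βA subunit, rose 21.3-fold (log2 4.42, and 3.75 without T-5224 replicate 1). HILPDA, a lipid droplet protein, fell 34.8-fold, from 103 ± 35.1 to 2.98 ± 1.26 CPM, and DEPP1 fell 43.9-fold. In all, 936 genes rose and 1299 fell among 14225 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Of these 2235 genes, 1697 changed at least 2-fold, 692 upward and 1005 downward. In 3330 genes the libraries of the groups did not overlap, 23.4% of those tested against 2.86% by chance. The count changed when single libraries were left out, which also leaves fewer libraries to detect a change. A call lost in such a fit need not mean a smaller change. It was 3705 without T-5224 replicate 2, 1239 without T-5224 replicate 3, and 1449, 1186 and 1136 without hCG replicates 1, 2 and 3.

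Further large rises were those of STMN4 (56.2-fold), PHKG1 (22.9-fold), DNAH17 (20.6-fold) and NR1D1 (19.4-fold), a nuclear receptor of the circadian clock. BRINP2, ARC and F2RL3 rose by log2 5.26, 4.77 and 4.26, and by 3.13, 3.61 and 3.18 without T-5224 replicate 2. STMN4 rose by log2 5.81, and by 5.12 without that library. DNAH17 rose by 4.37, and by 3.68 without T-5224 replicate 3. The call of BRINP2 ended with limma voom (adjusted p = 0.0687). Among the falls, GDF6, a growth factor of the BMP family, fell 57.2-fold, TICRR 40.8-fold, ALOX15B 38.9-fold, HS3ST1 36.2-fold and the antisense RNA FAM83A-AS1 32.5-fold. The value of GDF6 was log2 -5.84, and -6.49 without T-5224 replicate 1. CD24 fell 52.2-fold (log2 -5.71, and -5.12 without hCG replicate 2), its call ended with limma voom (adjusted p = 0.106), and its reads can be shared with near-identical copies. A few genes were nearly absent with T-5224. RTN4RL1 had 423 reads over the hCG group and 1 over the T-5224 group, a ratio of 349 once scaled for library size (95% counting interval 62.3 to 13820). SLC8A3, a sodium-calcium exchanger, had 273 and 1, a ratio of 225 (40.1 to 8934). EGLN3, an oxygen-sensing prolyl hydroxylase, had 269 and 2, a ratio of 111 (30.4 to 921.5). MIR503HG had 672 and 4. The fitted log2 fold changes of these genes moved when the library with the few reads was left out: RTN4RL1 from -7.96 to -9.66 and MIR503HG from -7.00 to -10.31 without T-5224 replicate 4, and SLC8A3 from -7.33 to -9.00 without T-5224 replicate 3.

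Of 18 tested genes of the AP-1 family and related bZIP factors, 7 rose, 2 fell and 9 did not pass. FOSB rose 7.83-fold, from 5.38 ± 2.21 to 42.2 ± 6.52 CPM (SD, n = 4 per group). ATF3 rose 9.73-fold, FOSL1 3.22-fold, JUND 2.85-fold and ATF4 2.65-fold, whereas MAF fell 7.31-fold. FOS, at chromosome 14, 75278778 to 75282234 on GRCh38.p6, had 122 ± 61.2 CPM with hCG and 44.4 ± 13.3 CPM with T-5224 (SD, n = 4 per group). It fell by 1.46 on the log2 scale (SE 0.44, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.0479). Without hCG replicate 4, where FOS lay at 33.8 CPM, the adjusted p was 0.00362 in the same edgeR test. Leaving out any of the other 7 libraries ended the call, with adjusted p from 0.0551 to 0.127 (edgeR, Benjamini-Hochberg), and so did limma voom (0.107) and a block on the replicate number (0.146). The log2 fold changes of JUN (0.86, SE 0.34), FOSL2 (0.41, SE 0.33) and JUNB (-0.03, SE 0.38) did not pass, though JUN passed without T-5224 replicate 2 (1.11) and with DESeq2 (0.86, adjusted p = 0.0493). In this list 9 genes passed when adjusted over the list alone. The list rose (camera adjusted p = 0.000747, and adjusted p = 0.0861 with an estimated correlation).

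In the unfolded protein and amino acid stress response, 13 of 20 genes rose and 2 fell. DDIT3, the stress transcription factor CHOP, rose from 10.96 ± 4.10 to 459 ± 407 CPM (SD, n = 4 per group), a log2 change of 5.39 that was 4.63 without T-5224 replicate 2. TRIB3, a pseudokinase induced by that pathway, rose 12.8-fold, SLC7A11, the cystine transporter, rose 11.7-fold, and PPP1R15A rose 7.04-fold. Of the members, 16 were higher and 2 lower adjusted over the list alone, and VLDLR fell 3.39-fold. The list had a median log2 fold change of 1.95 (camera adjusted p = 2.68e-19, and adjusted p = 0.0558 with an estimated correlation). In the list of NRF2 and oxidative stress genes, 4 of 20 rose and none fell, and the same number passed adjusted over the list alone. HMOX1, which degrades haem, rose 10.2-fold, TXNRD1 2.40-fold and GCLC 2.41-fold. TXNRD1 lost its call without hCG replicate 2 or 3 (adjusted p = 0.0569 and 0.0611), and GCLC without hCG replicate 1, 3 or 4 or T-5224 replicate 1 or 3 (0.106, 0.0996, 0.0824, 0.0693 and 0.1). The list rose (camera adjusted p = 0.000747, and adjusted p = 0.122 with an estimated correlation).

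Among cytokine genes, immediate early genes and genes known as AP-1 targets, more rose than fell. CXCL8, a neutrophil chemokine, rose from 55.0 ± 27.6 to 892 ± 471 CPM (SD, n = 4 per group), 16.2-fold. CXCL3 rose 9.11-fold, CXCL2 8.32-fold and IL1A 7.12-fold; CXCL2 and CXCL3 are close paralogs, so their levels are uncertain where reads align equally well to both. Of 17 cytokine genes 7 rose and 1 fell, and 10 passed adjusted over the list alone (camera adjusted p = 0.00129, and adjusted p = 0.126 with an estimated correlation). Of 21 textbook AP-1 targets 7 rose and 2 fell, and 11 passed adjusted over the list alone (camera adjusted p = 0.00148, and adjusted p = 0.351 with an estimated correlation). Among these, DUSP1, a MAP kinase phosphatase, rose 3.62-fold. Of the AP-1 targets that rose, only HBEGF is in no other list. CXCL8, IL6 and LIF are also in the cytokine list, and HMOX1, FOSL1 and DUSP1 are in other lists that rose. Of 24 cAMP-responsive and immediate early genes 8 rose and 2 fell, and 12 passed adjusted over the list alone (camera adjusted p = 0.00604, and adjusted p = 0.559 with an estimated correlation). NR4A1 rose 7.48-fold and KLF6 3.41-fold, and CITED2 fell 5.91-fold. That last list lost its call without hCG replicate 4 (camera adjusted p = 0.0705) and did not pass fry's directional test (adjusted p = 0.102).

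Ovulatory genes that hCG is known to induce split in both directions. PTX3 and HAS2, which build the cumulus matrix, fell 7.78-fold and 21.7-fold. The matrix protease ADAMTS9 fell 5.21-fold and the transcription factor RUNX1 3.54-fold. The value of HAS2 was log2 -4.44, and -5.12 without T-5224 replicate 2. AREG, an EGF-like factor, rose 2.88-fold, from 1282 ± 476 to 3696 ± 1084 CPM (SD, n = 4 per group), and lost its call without hCG replicate 2 or 3 (adjusted p = 0.0512 and 0.0537, edgeR, Benjamini-Hochberg). TNFAIP6, a matrix-linking protein, rose 3.99-fold (log2 1.99, and 2.60 without hCG replicate 2). It lost its call without hCG replicate 1, 3 or 4 or T-5224 replicate 1 or 3 (adjusted p = 0.0997, 0.109, 0.0735, 0.0549 and 0.081), without a filter (0.0678) and with the length trend removed (0.063). The protease gene ADAMTS1 fell 4.51-fold and lost its call without hCG replicate 1, 2 or 3 or T-5224 replicate 3 (adjusted p = 0.0624, 0.0701, 0.0665 and 0.0556). ANGPTL4 fell 5.17-fold (log2 -2.37, and -3.19 without T-5224 replicate 2). The progesterone receptor gene PGR (log2 -0.33, SE 0.72), PTGS2 (1.30, SE 0.62) and EREG (1.37, SE 0.60) did not pass, though PTGS2 and EREG did with the replicate block (adjusted p = 0.0199 and 0.029, edgeR). Of 27 members 5 rose and 8 fell, and 14 passed adjusted over the list alone, while the list did not pass (camera adjusted p = 0.106). It passed without hCG replicate 4 (camera adjusted p = 0.00476) or T-5224 replicate 1 (camera adjusted p = 0.0375).

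In prostaglandin signalling, PTGER2, a prostaglandin E2 receptor, fell 7.02-fold and the uptake carrier SLCO2A1 fell 5.68-fold. PTGES, a prostaglandin E synthase, fell 1.97-fold and lost its call without hCG replicate 1, 2 or 3 or T-5224 replicate 3 (adjusted p = 0.0522, 0.0518, 0.0596 and 0.0535). ABCC4 fell 2.70-fold and lost its call without hCG replicate 1, 2 or 3 or T-5224 replicate 3 or 4 (adjusted p = 0.0909, 0.0918, 0.0807, 0.0907 and 0.0805) and with limma voom (0.0521). Of 17 members 5 fell and none rose, and 5 passed adjusted over the list alone. The list did not pass (camera adjusted p = 0.0902), though it did without hCG replicate 4 (camera adjusted p = 0.033). It also passed fry's directional test (adjusted p = 0.01575).

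Among genes of cholesterol and fatty acid synthesis, some fell and none rose. CYP51A1, a sterol demethylase, fell from 1185 ± 127 to 397 ± 83.6 CPM (SD, n = 4 per group), SQLE fell 2.92-fold, MVK 2.89-fold and LSS 2.59-fold. Of 20 cholesterol synthesis genes 9 fell and none rose, with 13 adjusted over the list alone (camera adjusted p = 8.44e-07, and adjusted p = 0.126 with an estimated correlation). Of 23 genes of cholesterol uptake, storage and SREBP control 4 fell, with 6 adjusted over the list alone (camera adjusted p = 0.000119, and adjusted p = 0.126 with an estimated correlation). MYLIP fell 9.85-fold and INSIG2 3.60-fold. In fatty acid and triglyceride synthesis 7 of 21 fell, also adjusted over the list alone (camera adjusted p = 6.69e-05, and adjusted p = 0.274 with an estimated correlation). ACSL1 fell 5.33-fold, FADS1 3.93-fold, ACSS2 3.81-fold and the fatty acid synthase gene FASN 3.52-fold.

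Of 24 genes of glycolysis and glucose uptake 6 fell, 18 did not pass and none rose. PFKFB4, which makes an activator of glycolysis, fell from 282 ± 59.9 to 22.05 ± 4.28 CPM (SD, n = 4 per group), 12.8-fold. Its relative PFKFB3 fell 7.72-fold, the glucose transporter gene SLC2A1 7.28-fold and LDHA 2.40-fold. The list fell, with 9 lower adjusted over the list alone (camera adjusted p = 1.81e-06, and adjusted p = 0.126 with an estimated correlation).

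**Figure D2:**
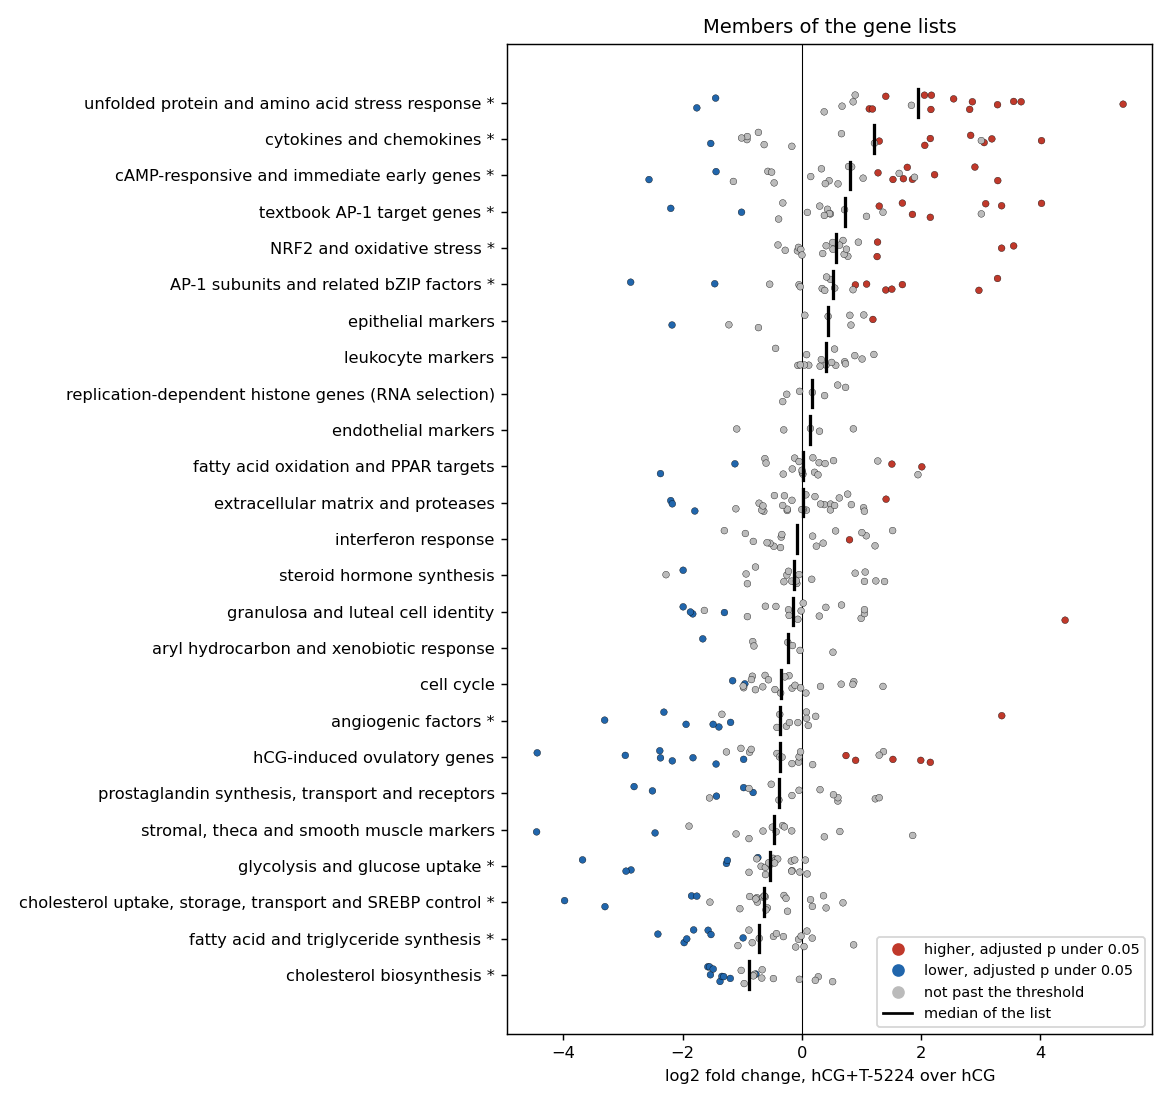
Log2 fold change of each tested list member, hCG+T-5224 over hCG, with 1 point per gene, the list median as a bar and an asterisk where camera passed at an adjusted p of 0.05. The unfolded protein and amino acid stress list has the highest median, 1.95, and cholesterol biosynthesis the lowest, -0.89.

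Steroid synthesis genes mostly did not pass. STAR, which carries cholesterol into mitochondria, had 5507 ± 1279 CPM with hCG and 5172 ± 1933 CPM with T-5224 (SD, n = 4 per group), and CYP11A1 had 7507 ± 2518 and 7277 ± 1655. The log2 fold changes were -0.09 (SE 0.32) and -0.04 (SE 0.30), and those of HSD3B2 (-0.78, SE 0.38), CYP19A1 (-0.91, SE 0.36) and the LH receptor gene LHCGR (-0.07, SE 0.23) did not pass either. HSD3B2 passed at -1.21 without T-5224 replicate 4, and CYP19A1 passed with DESeq2 (adjusted p = 0.039). Of 19 members 1 fell, also adjusted over the list alone: NR5A2, a nuclear receptor of steroidogenic cells, fell 3.97-fold. The list did not pass camera (adjusted p = 0.494) but passed fry's directional test (adjusted p = 0.03535). Of 20 granulosa and luteal identity genes 1 rose and 4 fell, and 5 passed adjusted over the list alone. That list did not pass camera (adjusted p = 0.226) but passed fry's directional test (adjusted p = 0.0381). The transcription factor genes GATA4 and GATA6 fell 2.46-fold and 3.55-fold. GATA4 lost its call without hCG replicate 2 (adjusted p = 0.0554), and GATA6 without hCG replicate 2 or 3 or T-5224 replicate 1, 3 or 4 (0.0657, 0.0557, 0.0506, 0.0684 and 0.0572). The angiogenic list fell, with 1 of 17 higher, 6 lower and 8 passing adjusted over the list alone (camera adjusted p = 0.0388, and adjusted p = 0.486 with an estimated correlation). FGF2 rose 10.2-fold in that list and PDGFA fell 3.84-fold. APLN fell 9.89-fold (log2 -3.31, and -3.93 without T-5224 replicate 2), and SEMA3A fell 2.62-fold and lost its call without hCG replicate 2 or 3 (adjusted p = 0.0621 and 0.06). The call of the list ended without hCG replicate 1, T-5224 replicate 2 or T-5224 replicate 4 (camera adjusted p = 0.0651, 0.0724 and 0.117).

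**Figure D3:**
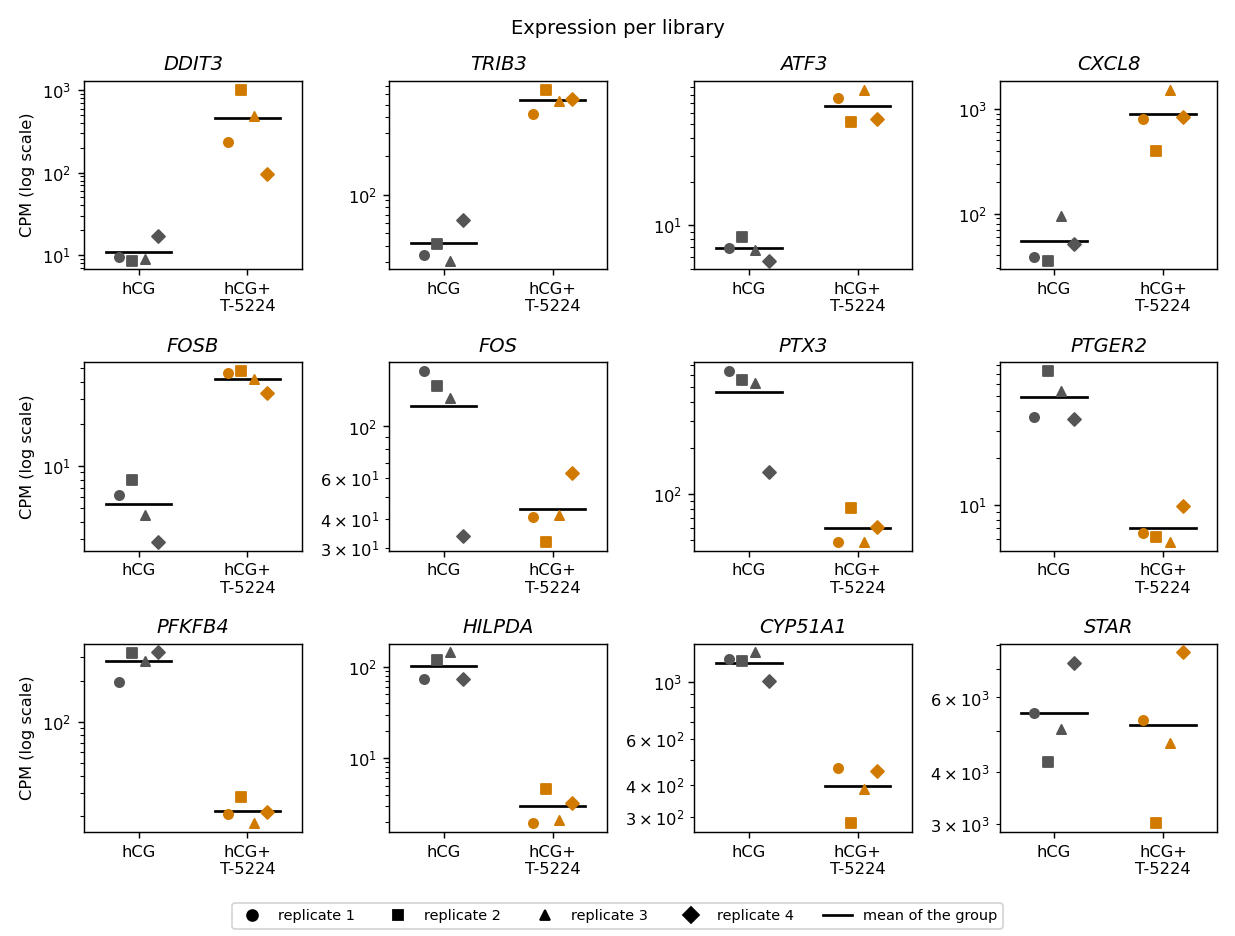
CPM on a log axis in each library for 12 named genes, with replicate numbers as marker shapes and the group mean as a line. DDIT3, TRIB3, ATF3, CXCL8 and FOSB lie higher in every T-5224 library than in any hCG library, whereas FOS and STAR overlap between the groups.

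The other lists did not pass. Fatty acid oxidation and PPAR targets had 2 higher and 2 lower of 21, and 4 adjusted over the list alone, with PPARG 4.03-fold higher (camera adjusted p = 0.546). PPARA fell 2.18-fold and lost its call without hCG replicate 1, 2 or 3 or T-5224 replicate 3 (adjusted p = 0.0694, 0.0822, 0.0747 and 0.0832) and with the replicate block (0.0624). FABP3 rose 2.85-fold and lost its call without hCG replicate 1, 2 or 3 or T-5224 replicate 4 (adjusted p = 0.0894, 0.0942, 0.0972 and 0.0505). The aryl hydrocarbon list had 1 lower of 7, also adjusted over the list alone (camera adjusted p = 0.455). This was TIPARP, 3.16-fold lower, whose call ended without hCG replicate 2 or T-5224 replicate 3 (adjusted p = 0.0513 and 0.0552). Extracellular matrix and proteases had 1 higher and 3 lower of 30, and 4 adjusted over the list alone (camera adjusted p = 0.494), with LAMB1 3.47-fold lower. ADAMTS5 rose 2.66-fold and lost its call on leaving out hCG replicate 1, 2, 3 or 4 (adjusted p = 0.0967, 0.064, 0.0998 and 0.0685) or T-5224 replicate 1 or 3 (0.0598 and 0.113), without a filter (0.0978) and with the replicate block (0.0526). The median of the matrix list was 0.01 while its mean (-0.11) and test lay below 0. The cell cycle list had 2 lower of 23 (camera adjusted p = 0.166) and the interferon list 1 higher of 18 (camera adjusted p = 0.935), with 0 in each adjusted over the list alone. In these, TYMS and CCNB1 fell 2.23-fold and 1.94-fold and HERC5 rose 1.74-fold. TYMS lost its call without hCG replicate 2, 3 or 4 or T-5224 replicate 1, 3 or 4 (adjusted p = 0.123, 0.0978, 0.0599, 0.0658, 0.074 and 0.0669). Without hCG replicates 1, 2 and 3 and T-5224 replicates 1, 3 and 4 in turn, CCNB1 lost its call (adjusted p = 0.132, 0.126, 0.108, 0.0908, 0.0873 and 0.0899), as did HERC5 (0.0566, 0.112, 0.12, 0.0682, 0.0913 and 0.062). Both also lost it without a filter (0.0988 and 0.129) and with the replicate block (0.0619 and 0.0605). The interferon median was -0.08 while its mean (0.07) and test lay above 0.

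Markers of other cell types were examined in the same way. None of 17 leukocyte and none of 5 endothelial markers passed, over all genes or adjusted over the list alone (camera adjusted p = 0.225 and 0.978). The smallest p belonged to CD68 (log2 0.72, SE 0.37), which passed with the replicate block in DESeq2 (adjusted p = 0.00854) and with quality weights (0.00936), and to PECAM1 (log2 -1.09, SE 0.75). The leukocyte list passed without hCG replicate 3 (camera adjusted p = 0.0165), and the endothelial median (0.15) and mean (-0.02) differed in sign. Of 9 epithelial markers 1 rose and 1 fell, with 3 adjusted over the list alone (camera adjusted p = 0.669), and CLDN4 fell 4.52-fold. KRT18 rose 2.29-fold and lost its call without hCG replicate 1, 2 or 3 or T-5224 replicate 3 (adjusted p = 0.0765, 0.0868, 0.0851 and 0.0719) and with the replicate block (0.0701). Of 14 stromal and theca markers 2 fell, with 3 adjusted over the list alone (camera adjusted p = 0.06). PTCH1, the Hedgehog receptor, fell 21.8-fold and NR2F2 5.50-fold. The stromal list passed without hCG replicate 4 (camera adjusted p = 0.00223) or T-5224 replicate 1 (camera adjusted p = 0.0331), and with a block on the replicate number (camera adjusted p = 0.00695). None of 7 histone genes passed, over all genes or adjusted over the list alone (camera adjusted p = 0.942), H1-2 having the smallest p (log2 0.60, SE 0.35, and -0.035 with the length trend removed).

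The share of counts on mitochondrial ribosomal and transfer RNA genes was lower in every T-5224 library than in any hCG library. Mitochondrial messenger RNAs were not among the counted genes. Of 10 tested mitochondrial genes, chosen after their values were seen, 9 fell and none rose. The 16S ribosomal RNA gene RNR2, at mitochondrial positions 1671 to 3229 on GRCh38.p6, fell 4.87-fold, from 11470.0 ± 2051 to 2358 ± 878 CPM (SD, n = 4 per group). The 12S ribosomal RNA gene RNR1 fell 2.80-fold, and 7 of 8 transfer RNA genes fell.

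In all, 11 of 25 tested lists passed with the preset correlation, 6 higher and 5 lower. Each of the 11 except the cAMP-responsive and immediate early list also passed fry's directional test, which asks whether the genes of a list move on balance 1 way. Some of these lists share members, such as ATF3, ATF4, SLC7A11, HMOX1 and CXCL8, so the 11 are not separate results. With an estimated correlation camera passed 0 of 25 (smallest adjusted p = 0.0558). Fry's directional test passed 13, among them the prostaglandin, steroid synthesis, and granulosa and luteal identity lists, which camera did not pass. In 3 other splits of the 8 libraries into groups of 4, 12 lists passed. Each of these splits kept 3 hCG libraries together and so still holds part of the treatment difference.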

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

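The tests of T-5224 replicate 2 alone, of mitochondrial stress, of poly(A) selection, of HIF activity, and of length trend, wrong label and cell type for T-5224 replicate 2 were chosen only after the result was seen. Removal of the length trend was itself added after seeing the data, though its predictions for the mitochondrial and glycolysis patterns were written before its values were seen. Among 218 groups of 4 values, 21 (9.63%) held a value past Dixon's gap ratio, against about 5% by chance; on log2 values 22 gene groups did. Of the 21, 7 lay in hCG replicate 4 and 6 in T-5224 replicate 2.

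The hCG replicate 4 library stood apart from the other hCG libraries, in CPM, at DDIT3 (17.1), GDF6 (2.86), HS3ST1 (6.70), MVK (68.0), CITED2 (564), FABP3 (162) and ADAMTS1 (9.72). For ADAMTS1 the other hCG libraries held 36.4 to 39.2 CPM, and for HS3ST1 35.2 to 39.8. GATA4 stood apart in hCG replicate 2 at 135 CPM. T-5224 replicate 2 stood apart at BRINP2 (20.1), F2RL3 (25.4), SLC2A1 (62.1), ANGPTL4 (487), GATA6 (103) and FOSL1 (151). T-5224 replicate 3 stood apart at CXCL3 (55.0) and ADAMTS5 (3.17), and T-5224 replicate 4 at PDGFA (6.02) and TYMS (7.65). RTN4RL1 (0.0627), SLC8A3 (0.0566) and MIR503HG (0.251) stood apart because 1 T-5224 library held all of the few reads.

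In these libraries the mitochondrial 16S ribosomal RNA gene RNR2 was 4.87-fold lower with T-5224. It stayed lower with each library's trend on gene length removed (log2 -2.42) and without T-5224 replicate 2 (log2 -2.06), which argues against either as the whole cause. Histone genes had a median log2 fold change of 0.18, but most of the 7 tested are known to also make polyadenylated transcripts, so a difference in poly(A) selection stays open. Of 8 mitochondrial transfer RNA genes 7 fell. Removal of ribosomal RNA would not directly lower those away from the ribosomal RNA genes, such as TRNG (22.5-fold lower, from position 9991). TRNL1 starts at position 3230, next to the end of RNR2, so its reads may go with those of RNR2. Whether the reads came from mature transfer RNA was not tested. A share of ribosomal RNA removal in the fall of RNR2 stays open. A list of mitochondrial stress genes had a median log2 fold change of 0.83, and 0.81 without CEBPG, seen beforehand (camera adjusted p = 0.0022, and adjusted p = 0.148 with an estimated correlation). Of its 17 genes 8 rose and 1 fell. It holds amino acid stress genes such as AARS1, and the unfolded protein and amino acid stress list had already been seen to rise. Its rise therefore cannot tell a mitochondrial stress response from that one. Its mitochondrial protease genes LONP1 (log2 -0.11) and CLPP (0.22) did not pass, while the mitochondrial chaperone gene HSPA9 rose (0.83).

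T-5224 replicate 2 lay apart from the other T-5224 libraries on the first principal component (118.8 against 16.9 to 31.2). Shallower sequencing was argued against, because the other T-5224 libraries, thinned to its total, listed at least 2797 more genes with a read. Its deviation from the other T-5224 libraries fell with gene length (Spearman rho -0.367 across genes, which are not independent replicates), but hCG replicate 4 reached -0.42, so the length trend stays open. The 0.454 of T-5224 replicate 1 was taken against a mean that includes replicate 2 and is no separate comparison. T-5224 replicate 2 had a mean gene length per read of 3315, against 3923 to 4602 in the other libraries. Of the 3615 genes that were called without it and were also among the 14225 tested with it, it lay on the T-5224 side in 65.7%, and its mitochondrial share (0.126%) was below every hCG library, which speaks against an hCG library but leaves a wrong label of another kind open. The largest median difference among 4 other-cell-type lists was 0.936, for epithelial markers, too small to decide whether cells of another type were present.

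Glycolysis and glucose uptake genes were lower with T-5224. The median stayed at log2 -0.46 with the length trend removed and at -0.51 without T-5224 replicate 2, which argues against both as the whole cause. Lower HIF activity is a candidate explanation, as 39 HIF targets outside the fixed lists had a median of -1.15. The fall was not uniform: 19 fell, 20 did not pass and none rose. CA9 (log2 -0.57) and NDRG1 (-0.41) were among those that did not pass. That list was written after EGLN3 and HILPDA had been seen to fall, and without these 2 genes the median was -1.08 (camera adjusted p = 3.16e-12, and adjusted p = 0.0663 with an estimated correlation). A direct action of T-5224 and a general toxic effect were not separated by these data.

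All 35 splits of the 8 libraries into 4 and 4 were tested. For the genes changed, 1 split, the real one, reached 2235 calls and the highest other gave 0. If the libraries are independent, 1 of 35 is a share under 0.05, the smallest that these splits allow. This argues against chance without excluding it. Every other split mixes hCG and hCG+T-5224 libraries within its groups, which raises the spread there and lowers the calls. For the AP-1 list, 1 split reached 9 members and the highest other gave 0, which follows from the gene counts and is no separate evidence. If the replicate numbers mark shared cultures, which stays open, exchanges within the pairs give 8 splits, too few for a share under 0.05. For the lists moved, 4 splits reached 11 and the highest other gave 12, so this test does not exclude chance. Those 3 other splits kept hCG replicate 4 and 2 further hCG libraries together with a T-5224 library. They still hold part of the treatment difference and do not show what chance alone gives. Splits with 2 hCG libraries in each group gave at most 9 lists.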

How the results depend on the processing

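Quality weights and removal of the length trend were the alternatives chosen after seeing the data. Of 2413 values of named genes under alternatives, 2164 kept direction and side of the threshold, 205 lost and 26 gained a call, and 18 reversed, none of them a called gene. Fits without 1 library rest on fewer libraries, and some calls ended there with no smaller change. Without hCG replicate 2, for instance, PTGES went from log2 -0.976 to -0.981 and ADAMTS5 from 1.41 to 1.56. Of 523 list values, 476 kept both, 9 lost a call, 20 gained one and 18 reversed. Depth limits genes with few reads. In the simulated counts, which held far fewer changed genes than were called here, 4 libraries per group recovered 9.67% of 2-fold changes. Such changes can be missed here too, but the share missed in these data was not measured. Unless given, the cause was not tested.

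The labels do not say whether a replicate number marks a shared culture. Deviations of same-numbered libraries correlated at 0.348 to 0.469 in pairs 1, 3 and 4 and at 0.0347 in pair 2, and 3 of 4 libraries in each group correlated best with their own number, a hint of pairing from the data. Because pair 2 lay below the required 0.1, the numbers were not treated as pairs in the main test, and pairing stays open. Pair 2 holds T-5224 replicate 2, which lay apart from its group, so the low value of that pair does not settle the question. With the replicate block 1996 genes were called, 1779 of them shared with the main 2235 in the same direction. In that fit FOS lost its call, and PTGS2 and EREG gained one. With numbered pairs 1, 2, 3 and 4 left out of the block fit, 561, 5121, 284 and 789 genes were called (189, 2461, 99 and 264 higher, 372, 2660, 185 and 525 lower), and pairs 1 and 3 left 4 and 3 AP-1 members. These fits rest on fewer libraries.

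DESeq2 called 3469 genes, 1625 of them higher. An adjusted p under 0.01 left 907 (344 higher, 563 lower), by construction. Quality weights gave 7200 (3606 higher, 3594 lower) and 14 AP-1 members, with weights of 0.104 for T-5224 replicate 2 and 5.87 for hCG replicate 3. Leaving out 1 library gave 1136 to 3705 genes, 417 to 1637 higher and 719 to 2068 lower. Without T-5224 replicate 2, 99.6% of the 2235 genes were called again in the same direction. An estimated correlation left 0 lists. Normalization moved the median of all genes by at most 0.02.

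Uncalled genes that changed sign, as log2 ranges over single libraries left out, were JUNB (-0.53 to 0.22), PGR (-0.70 to 0.16), STAR (-0.34 to 0.095), CYP11A1 (-0.18 to 0.20) and LHCGR (-0.21 to 0.053). In the block fit without a pair, JUNB was 0.086 (pair 1), PGR 0.025 (pair 2) and CYP11A1 0.058 (pair 4). Quality weights gave CYP11A1 0.17 and LHCGR 0.10, and the length trend removed gave LHCGR 0.034 and H1-2 -0.035. Uncalled lists whose test changed direction were interferon (-0.32 to 0.028 over libraries left out, -0.37 without a filter, -0.26 without pair 2), endothelial (-0.55 to 0.77, 0.13 with quality weights, 0.24 with the length trend removed), epithelial (-0.043 to 0.69, 0.030 without pair 2) and histone (-0.037 to 0.31, -0.050 with voom, -0.027 with the stricter filter, -0.050 and -0.22 without pairs 1 and 3, -0.18 with the length trend removed).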

Other observations

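Further gene groups were chosen after the data had been seen and are therefore not independent evidence. Circadian clock genes changed in both directions: of 18 tested, 7 rose and 5 fell. The repressor genes NR1D1 and NR1D2 rose 19.4-fold and 10.2-fold, and NFIL3 rose 5.60-fold, while BHLHE41 fell 9.29-fold and BMAL1, an activator of the clock, fell 2.68-fold. As a list they did not pass (camera adjusted p = 0.174). Of 39 HIF targets outside the fixed lists 19 fell and none rose (camera adjusted p = 7.67e-15, and adjusted p = 0.0649 with an estimated correlation). CYGB fell 16.1-fold, ZNF395 5.62-fold and EGLN1 3.52-fold. Of 7 Hedgehog pathway genes 5 fell, PTCH1 among them (camera adjusted p = 8.84e-05, and adjusted p = 0.048 with an estimated correlation). Without PTCH1, which had been seen beforehand, the latter was adjusted p = 0.0663. Of 10 BMP and ID genes 3 fell, ID2 by 12.6-fold (camera adjusted p = 0.00215, and adjusted p = 0.0649 with an estimated correlation).

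Of 19 heat shock and chaperone genes 6 rose (camera adjusted p = 0.000292, and adjusted p = 0.116 with an estimated correlation). HSPA1A rose 6.08-fold and HSPA1B 3.32-fold. These are near-identical copies, so their levels are uncertain where reads align equally well to both. Of 8 metallothioneins 2 rose, with camera adjusted p = 0.0109 (adjusted p = 0.437 with an estimated correlation), and the call ended without T-5224 replicate 2 (camera adjusted p = 0.0587). Of 17 mitochondrial stress genes 8 rose and 1 fell (camera adjusted p = 8.84e-05, and adjusted p = 0.0801 with an estimated correlation). Of 16 p53 targets 4 rose and 1 fell (camera adjusted p = 0.0102, and adjusted p = 0.0649 with an estimated correlation). The other 11 did not pass, MDM2 (log2 0.33) and BAX (0.12) among them. None of 33 nuclear-encoded respiratory chain genes passed singly, while the list rose (camera adjusted p = 0.0458, and adjusted p = 0.59 with an estimated correlation). That call ended without T-5224 replicate 2 (camera adjusted p = 0.241). Of 26 genes of mitochondrial transcription and DNA maintenance 2 rose and 5 fell (camera adjusted p = 0.398).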
